A study of Homo sapiens with 2 samples.

How the data were processed

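RNA from MCF-7 cells with an inducible construct for the intracellular domain of LRP1B was hybridised to 2 Affymetrix whole-transcript arrays, 1 of cells without doxycycline and 1 of cells with doxycycline at 100 ng/ml. The vector design, per the series design text, places the coding region of the domain under a doxycycline-responsive promoter in cells that stably express the Tet-On 3G transactivator. Several clones were made, and neither the clone each array came from nor the duration of the doxycycline treatment was given in the sources used here. Total RNA was extracted with a Qiagen kit and labelled as biotinylated cRNA, per the labels' protocols.

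The deposited values are intensity values on a linear scale, 1 per transcript cluster and array, for 53617 clusters. MAS5 is the only tool named, per the submitters' processing notes, and the background correction, summarisation, scaling and genome build were not given in the sources used here. Signals ran from 3.06 to 10341 with no value below 0, so they were read as linear and not as log2 values. Identical values on both arrays were held by 1543 clusters (2.88%). Between 100 and 1000, 5.88% of uninduced and 5.53% of induced values shared 1 remainder after division by 0.5, to within a bin of 0.001, where an even spread would put 0.2% in any bin. The method behind the values therefore stays open, and the name MAS5 is given only as the notes state it. The values were used as deposited.

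Gene names came from a platform probe table with 16098 clusters, each with 1 gene symbol and none with several, for 14884 symbols. Every Entrez ID matched the RefSeq gene table (assembly GRCh38.p14) and no symbol changed. That assembly was used for names, gene type, containment of 1 gene in another, genomic span and the order of neighbouring genes, and none of its positions is printed. The other 37519 clusters are unnamed here and entered no gene count, and 12 further clusters were left out on privacy grounds. A cluster was measured on an array when its signal was at or above the median of all values of both arrays (33.5), and a gene was represented by the measured cluster with the highest mean log2 signal. This left 25545 clusters measured on both arrays, 10993 of them named, and 10265 genes, of which 9098 were protein-coding. The log2 ratio is that of the induced over the uninduced signal with no pseudocount. Genes at or above the floor on 1 array only were given a bound against the floor, and genes below it on both were given no ratio.

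With 1 array per group no test was run and no p-value is given. Genes were counted at a size of 2-fold. The named genes followed a rule written before the data were examined. It took up to 12 genes each way with 2 or more clusters all past 1.5-fold in 1 direction (6 met it, all lower), the 5 highest and 5 lowest ratios, the 4 largest bounds each way, LRP1B, LRP1, ESR1, TFF1, PGR, NEAT1 and MALAT1 at any value, and 2 to 4 members of each gene list with the largest ratios. The remaining genes past 2-fold, host genes of microRNAs, other list members and the genes of the first paragraphs of the other observations were named after their values were seen. The 31 gene lists, with 714 distinct genes of which 462 were in the probe table and 415 were measured on both arrays, were also written beforehand. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins, and a list stood apart below percentile 2.5 or above 97.5. Lists with fewer than 5 measured genes got no percentile. These percentiles describe the pair of arrays and are no test of the conditions. Agreement between clusters of a gene was compared with 100 shuffles of the ratios within 10 bins of signal.

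Alternatives were median scaling, quantile normalization, lowess centring on signal, floors at the 25th and 75th percentiles, a pseudocount equal to the floor, the median over clusters of a gene, thresholds of 1.5-fold and 3-fold, random lists without matching, and lists without their largest member. Median scaling set equal the medians of the clusters measured on both arrays, not of all clusters. Protein-coding genes alone and centring within 20 bins of genomic span were added after the data were seen. The median log2 ratio of all genes was 0.016 as deposited, 0.084 after median scaling, 0.066 after quantile normalization and 0.006 after lowess centring. Checks of 3' to 5' control ratios and hybridisation spikes had been planned and were not run, because the control clusters carried no name here.

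The procedure was tested on simulated data made from the real mean signals, with noise of the robust spread of the real ratios in each signal decile. For the comparison of induced with uninduced arrays, 50 genes were simulated at each true difference. A true difference of 1.5-fold passed 2-fold in 2.1% of 48 measured genes, and a true difference of 2-fold in 54.8% of 42. A 3-fold difference passed in 100% of 43 measured genes and a 4-fold difference in 100% of 34. The rest of each 50 were below the floor on a simulated array and got no ratio. The shares leave them out and so overstate how many altered genes are found. Of 10090 unaltered genes, 0.01% passed. Of 100 simulated lists of 20 unaltered genes drawn from those 10090, 7 fell outside the central range, and of 100 lists shifted by 0.2, 87 did. That noise was normal and independent between clusters. Its spread includes real differences between the arrays but gives little weight to outlying ratios. The 0.01% of genes and the 7 of 100 lists are therefore no false-positive rates for this pair of arrays. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.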

Results

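Expression was measured in MCF-7 cells, an established estrogen receptor-positive human breast cancer line, that carried a doxycycline-inducible construct for the intracellular domain of LRP1B. LRP1B is a large receptor of the LDL receptor family, and the construct holds the part that lies inside the cell, with the green fluorescent protein ZsGreen1 encoded on the same vector. Of 2 whole-transcript arrays, 1 came from cells kept without doxycycline (0 ng/ml, called the uninduced array) and 1 from cells labelled as expressing the domain with doxycycline at 100 ng/ml (called the induced array). The comparison asks which transcripts differ when the intracellular domain is produced. With 1 array per group there are no replicates, so no difference was tested and each value describes these arrays rather than the conditions. The number of arrays limits the precision, and doxycycline itself cannot be told apart from the domain because no array of doxycycline-treated cells without the construct was analysed here. Any effect of ZsGreen1 cannot be told apart from the domain either. The same holds for a difference of clone, since the clone of each array was not given. The deposited values were close in level, with a median signal of 33.3 uninduced and 33.7 induced over 53617 transcript clusters. The scaling behind them was not given and may impose this closeness, so it does not describe the cultures. Across clusters, which are not independent replicates, the log2 signals had a Pearson correlation of 0.986. At or above the floor of 33.5 lay 26718 clusters (49.8%) of the uninduced array and 26899 (50.2%) of the induced array. The floor is the median of all values of both arrays, so shares of this size follow from its definition.

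LRP1B was examined first. Its only cluster (16903186) read 38.4 on the uninduced array and 25.2 on the induced array, which is at least 1.15-fold lower against the floor. This runs opposite to the label. A cluster that spans the whole transcript would lie mostly outside the short cloned part, but where its probes fall was not given in the sources used here. Whether the cluster can check the transgene is therefore unknown. Its reading gives the labels no support, and every direction given here rests on the labels alone. LRP1, the closest relative of LRP1B, read 40.4 and 49.5, a log2 ratio of 0.29. Genes that mark the hormone-responsive state of MCF-7 were nearly level. ESR1, the estrogen receptor itself, read 710.6 and 671, a log2 ratio of −0.08. TFF1, a secreted peptide induced by estrogen, read 6582 and 6498, a log2 ratio of −0.02, and PGR, the progesterone receptor, read 109.7 and 97.7, a log2 ratio of −0.17.

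A small number of genes differed by 2-fold or more. PEG10, an imprinted gene derived from a retrotransposon, was 3.04-fold higher on the induced array (121 uninduced, 369 induced, cluster 17048563). QPRT, an enzyme of NAD synthesis from quinolinate, was 2.75-fold higher (224 and 616, cluster 16817630), and MMP16, a membrane-anchored matrix metalloproteinase, was 2.28-fold higher (85.2 and 194, cluster 17078870). UBE2QL1 of the ubiquitin-conjugating enzyme family was 2.21-fold higher (118 and 261), and TFPI, the inhibitor of the tissue factor pathway of coagulation, was 2.2-fold higher (72.6 and 159.8). CEACAM6, a cell surface adhesion glycoprotein, had the largest ratio in size of the genes measured on both arrays and was 3.79-fold lower on the induced array (1039.7 and 274.5, cluster 16862563). GPX2, a glutathione peroxidase, was 3.0-fold lower (339 and 113, cluster 16793877). Among 10265 genes measured on both arrays, 6 were at least 2-fold higher and 22 at least 2-fold lower. TARP, which is transcribed from the T-cell receptor gamma locus, completed the higher group at 2.06-fold (73.3 and 151). The median log2 ratio over all measured genes was 0.016 with an SD of 0.244 across genes, and 97.4% of genes lay within 1.5-fold. Centring the arrays on the medians of the clusters measured on both, not of all clusters, gave 9 higher and 14 lower. Quantile normalization gave 9 and 15. Lowess centring gave 6 and 24, and span centring, added after the data were seen, gave 6 and 28. Of 50 genes simulated with a true 1.5-fold difference, 48 were measured and 2.1% of these passed 2-fold. Of 50 with a true 2-fold difference, 42 were measured and 54.8% of these passed.

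**Figure D1:**
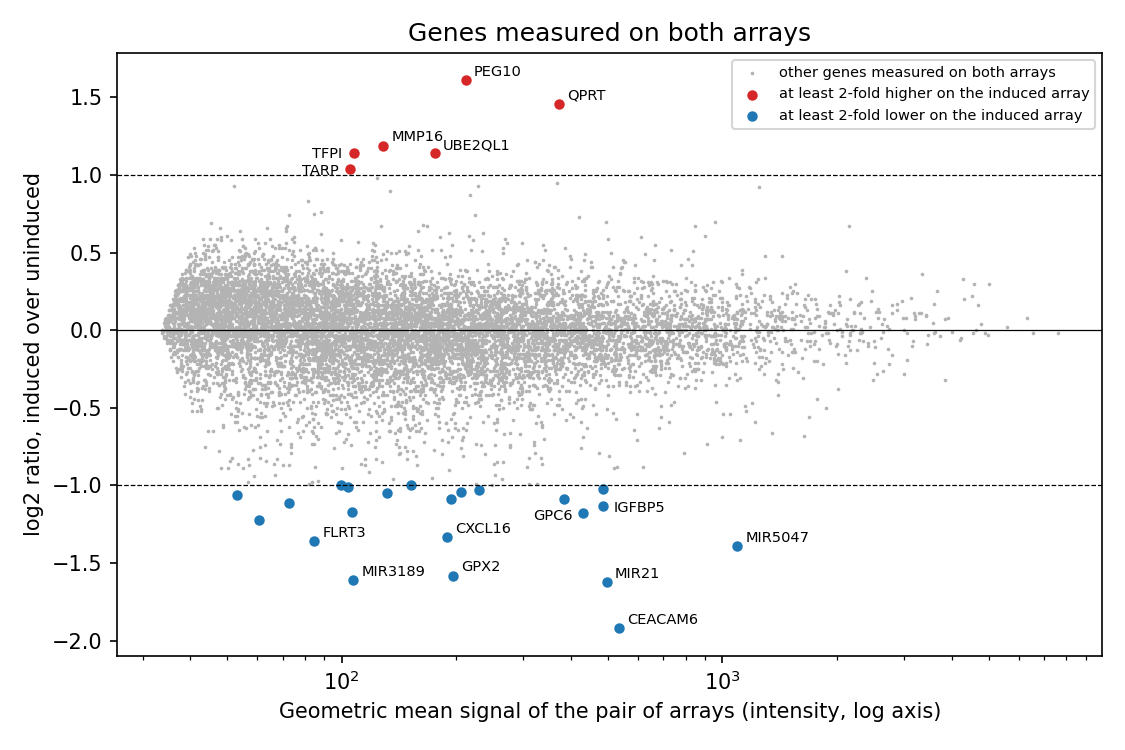
Each point is a gene measured on both arrays, with the geometric mean of its signals on a log axis and its log2 ratio of induced over uninduced signal on the other axis; dashed lines mark 2-fold. The 6 genes above the upper line reach 1.61 (PEG10), and the 22 genes below the lower line reach −1.92 (CEACAM6).

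FLRT3, a leucine-rich adhesion protein, was 2.56-fold lower (135 and 52.8), the chemokine CXCL16 was 2.51-fold lower (299 and 119), and the glypican GPC6 was 2.26-fold lower (649 and 287). IGFBP5, which binds insulin-like growth factors, was 2.19-fold lower (720.0 and 328). C1orf116 and C6orf141 had log2 ratios of −1.17 and −1.09, and the kinase HIPK2 stood at −1.0. HNRNPA1 had a log2 ratio of −1.09, RSRC2 of −1.03 and HMGN2 of −1.01. HNRNPA1 and HMGN2 have many processed pseudogenes, and ANKRD36B (−1.0) and the pseudogene WASH5P (−1.04) have near-identical copies, so the transcripts behind these clusters are uncertain. LOC729737, at −1.02 by its brightest cluster, had 5 clusters with a mean of −0.53 ± 0.40 (SD over clusters), and the median over clusters was −0.5. Of the 22 lower genes, 13 were protein-coding, whereas all 6 higher genes were. The split at 1.5-fold was 46 higher and 153 lower for protein-coding genes and 7 higher and 66 lower for all others.

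Clusters named for microRNAs made up 4 of the lower genes. MIR21 was 3.07-fold lower (869.5 and 283), MIR3189 was 3.06-fold lower (188 and 61.3), and MIR5047 was 2.62-fold lower (1769 and 675.5). Each of these lies inside a protein-coding gene whose own cluster was much closer to level. The log2 ratio was −0.03 for VMP1, which holds MIR21, −0.42 for GDF15, which holds MIR3189, and −0.28 for DDX5, which holds MIR5047. MIR1204, from the PVT1 locus, had a log2 ratio of −1.05. Such clusters read RNA at the hairpin's locus and do not by themselves measure the mature microRNA. The 347 measured microRNA genes had a median log2 ratio of 0.1, with 15 at least 1.5-fold lower and 4 at least 1.5-fold higher. The long non-coding transcripts LINC00641 (−1.22) and NFYC-AS1 (−1.11) and the pseudogene GCSHP3 (−1.06) also lay past 2-fold.

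**Figure D2:**
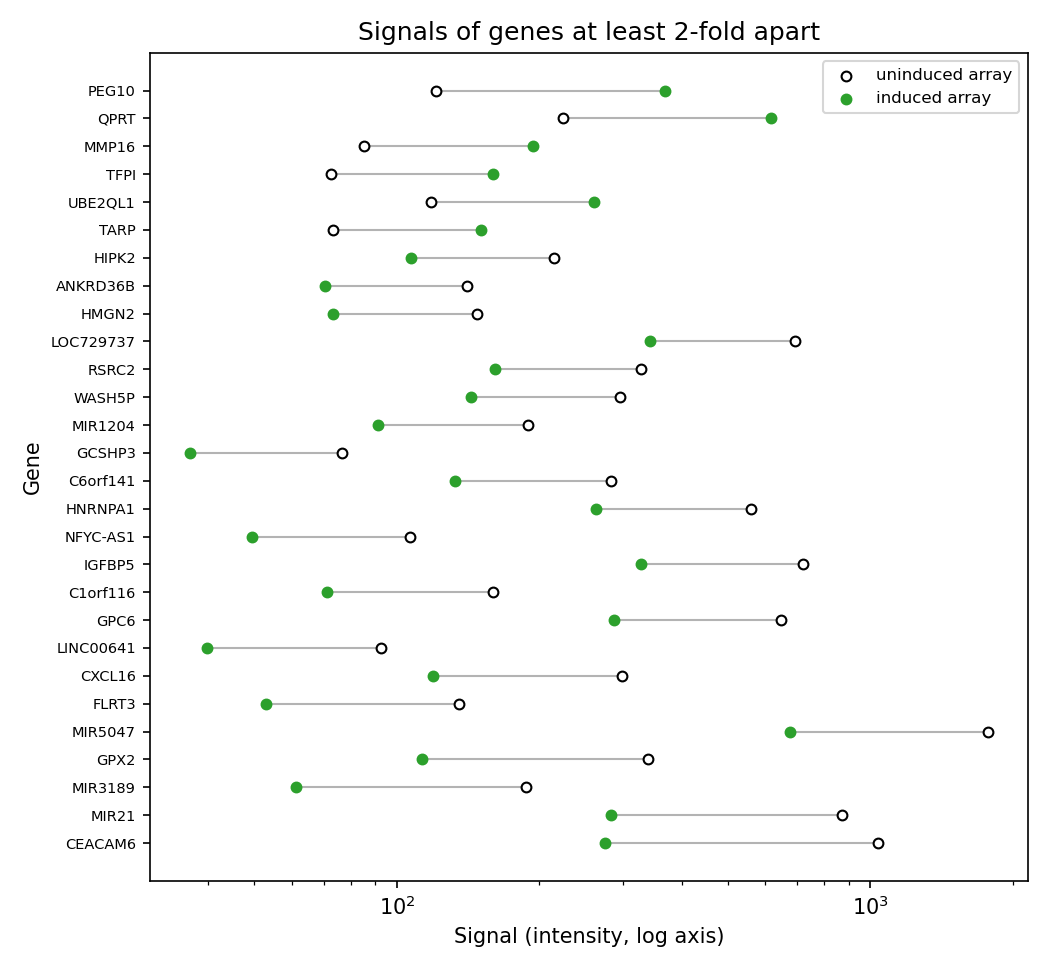
Signals (intensity, log axis) of the 28 genes at least 2-fold apart, 1 row per gene, with an open point for the uninduced array and a filled point for the induced array joined by a line. CEACAM6 spans 1039.7 to 274.5 and PEG10 spans 121 to 369; there is 1 array per point, so no error bars are drawn.

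Genes seen at or above the floor on a single array have only a bound. Their numbers count crossings of a floor set at the median signal, not genes switched on or off. Over all clusters the arrays were nearly even, with 26718 at or above the floor uninduced and 26899 induced. Clusters below the floor on both arrays had a median log2 ratio of 0.037. On the induced array alone were 367 genes, led by the long intergenic RNA LINC00052, which was at least 2.58-fold higher (30.4 uninduced, 86.4 induced). LOC729732 was at least 1.65-fold higher, TSPOAP1, a binding partner of a mitochondrial membrane protein, at least 1.59-fold, and MME, the cell surface peptidase neprilysin, at least 1.48-fold. On the uninduced array alone were 134 genes, led by MIR544B, which was at least 2.2-fold lower (73.7 and 26.0). SPRR1A, a protein of the cornified envelope of squamous epithelium, was at least 1.99-fold lower, MIR4720 at least 1.97-fold and MIR590 at least 1.92-fold. LINC00052 and MIR544B were the only genes in this class with a bound of 2-fold or more.

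Genes read by several clusters gave the only repeated measurement within the pair. Over 406 genes with 2 or more measured clusters, the SD between clusters of a gene was 0.16 on the log2 scale. It was 0.243 after the ratios were shuffled among clusters of like signal. For the 373 genes with 2 or more clusters of distinct values, the SD was 0.168. No gene had all its clusters past 2-fold. All clusters lay past 1.5-fold for 6 genes, each lower on the induced array, where shuffling gave 0.14 on average and at most 1. The shuffles treat clusters of a gene as independent. Clusters that share probes are not, so 0.14 may be too low a number for such genes. TRIM31, a ubiquitin ligase, had a mean log2 ratio of −0.82 ± 0.05 (SD over 5 clusters). Its clusters read 35.0 to 42.3 on the induced array, close to the floor of 33.5. RNF32 had −0.81 ± 0.24 (2 clusters), and the mismatch repair homolog MSH5 had −0.75 ± 0.08 (2 clusters). RGPD2 had a mean of −0.86 ± 0.01 (2 clusters) and the 2 clusters of RGPD6 read −0.83 and −0.82, but these are near-identical relatives of RANBP2 and their clusters cannot be assigned with certainty. The clusters of LOC100190986 held identical values (−0.88), so they count as 1 reading. TRIM31 and MSH5 lie in the major histocompatibility region, for which arrays can carry clusters of alternative haplotypes, so their clusters may repeat the same probes.

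Among the 29 lists written beforehand that had a percentile, long non-coding RNAs lay farthest from the random lists. All 13 measured members of the 26 listed had a log2 ratio below 0, against 46.4% of all genes, and the list median of −0.43 lay at percentile 0.0 of random lists matched on signal (their central range, without the outer 2.5% on each side, was −0.12 to 0.14). GAS5, a host of small nucleolar RNAs, was 1.63-fold lower (763 and 467), and the likewise snoRNA-hosting SNHG5 and ZFAS1 had log2 ratios of −0.5 and −0.47. MALAT1, the abundant nuclear RNA of speckles, read 2046 and 1386 in its brightest cluster, and its 3 clusters had a mean of −0.63 ± 0.13 (SD over clusters). MIR22HG stood at −0.55 and NORAD at −0.38. The lower position was not shared by all long non-coding RNA genes, since the 565 measured had a median of 0.0, with 30 at least 1.5-fold lower and 2 at least 1.5-fold higher. NEAT1, the scaffold of paraspeckles, was not analysed here because no cluster carried its name.

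Paraspeckle and nuclear speckle proteins, which include many splicing factors, were also lower. Of 22 measured members, 19 had a log2 ratio below 0 and 4 were at least 1.5-fold lower. SRSF5, a serine-arginine-rich splicing factor, was 1.98-fold lower (459 and 232), CLK1, the kinase that phosphorylates such factors, was 1.94-fold lower (189.9 and 97.7), SRSF11 stood at −0.83, and SFPQ, a core paraspeckle protein, at −0.65. The list median of −0.18 lay at percentile 0.0 (random range −0.10 to 0.09). PSPC1 (0.05), HNRNPK (0.08) and DAZAP1 (0.02) lay slightly above 0.

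The cell cycle lists lay on opposite sides of 0, a difference that was not itself tested. DNA replication and G1/S genes were slightly higher, with 15 of 22 measured members above 0 and a median log2 ratio of 0.10 at percentile 99.6 (random range −0.11 to 0.07). GINS2 of the replicative helicase stood at 0.45, the helicase subunit MCM2 at 0.35, the licensing factor CDT1 at 0.30 and thymidylate synthase, TYMS, at 0.29. Mitosis and G2/M genes were slightly lower, with 15 of 23 below 0 and a median of −0.10 at percentile 1.9 (random range −0.09 to 0.08). The checkpoint kinase BUB1 stood at −0.56 (491 and 334), the proliferation antigen MKI67 at −0.54 (1262 and 869.8) and the mitotic kinesin KIF20A at −0.35, while the survivin gene BIRC5 stood at 0.27. BUB1 lies on chromosome 2 between ANKRD36B and TTL, in a window of 50 neighbouring genes with a median of −0.3. Its ratio therefore cannot be told apart from that of its region. No member of either list reached 1.5-fold. The mitotic list moved inside the random range under quantile normalization (percentile 6.0) and lowess centring (5.9) and without BUB1 (8.2), and the replication list did so against random lists not matched on signal (95.8).

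Interferon response genes had a median log2 ratio of −0.12 over 11 of 27 listed genes, at percentile 2.3 (random range −0.12 to 0.20), with 8 below 0. The RNA sensor RIGI stood at −0.65, HERC6 at −0.49, the related sensor IFIH1 at −0.41 and the transcription factor IRF9 at −0.31. Basal and mesenchymal markers, of which 8 of 22 were measured, had a median of −0.18 at percentile 1.6 (random range −0.16 to 0.19) and 5 below 0, with fibronectin, FN1, at −0.47, the transcription factors SNAI2 and SNAI1 at −0.38 and −0.26, and EGFR at −0.21, against VIM at 0.17, MSN at 0.11 and AXL at 0.10. Both positions were marginal. The interferon list lost its place under 6 of its alternatives, for example at percentile 4.1 after lowess centring, and the basal list lay at percentile 4.1 without FN1. Of 29 lists with a percentile, 5 lay below the random range and 1 above it. By chance alone 1.5 would lie outside if the genes within a list varied independently. Genes of a list can vary together between any pair of cultures, so 1.5 may be too low a number for this comparison.

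Receptor and hormone groups stayed inside the random range. For these and the following lists, gene numbers count measured members, and each list had further members that were not read. The LDL receptor family had a median log2 ratio of −0.03 over 11 genes (percentile 28.0), with LRP11 at −0.52, LRP5 at −0.30 and LRP3 at 0.27. Genes of receptor shedding and the gamma-secretase, the protease that frees intracellular domains, had a median of −0.01 over 13 genes (percentile 44.0), with the sheddase ADAM17 at −0.31 and APH1B at 0.27. Estrogen receptor targets had a median of 0.0 over 21 genes (percentile 44.2), with STC2 at −0.5, RAPGEFL1 at −0.38 and OLFM1 at 0.34. Luminal epithelial markers had a median of 0.03 over 15 genes (percentile 69.4), among which AGR2, a secretory pathway disulfide isomerase, was at least 1.5-fold lower at −0.63, and TFF3 and SPDEF each stood at 0.27.

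Signalling and invasion lists also stayed inside, though some members stood apart. Invasion proteases and inhibitors had a median of 0.14 over 12 genes (percentile 97.3), and MMP16 and TIMP2 were at least 1.5-fold higher. TIMP2, an inhibitor of matrix metalloproteinases, was 1.82-fold higher (161 and 293). The membrane protease MMP14 stood at 0.38, with an uninduced signal of 35.8 close to the floor. The median of this list lay above the random range after median scaling, lowess centring and with a pseudocount. Immediate early genes had a median of −0.12 over 17 genes (percentile 3.1), with the transcription factors EGR1 at −0.86 (337 and 186) and JUN at −0.76 (553 and 326.5) and the phosphatase DUSP5 at 0.40. That list lay below the random range in 4 of its alternatives. The p53 targets had a median of −0.15 over 13 of 24 listed genes (percentile 3.5), with AEN at −0.43, GDF15 at −0.42 and BBC3 at 0.28. The other listed p53 targets, CDKN1A and MDM2 among them, were not in the probe table. The p53 list lay below the range in 3 alternatives. Notch targets had a median of 0.0 over 11 genes (percentile 49.4), although the ligand JAG1 was 1.76-fold lower (444 and 252) and HEY2 stood at 0.31. Wnt targets had −0.02 over 12 genes (percentile 31.7, FZD7 −0.37, APCDD1 −0.31). TGF-beta targets had 0.09 over 9 of 18 listed genes (percentile 84.2, SKI −0.43, LTBP2 0.39) with a mean of 0.0. The NF-kB and inflammatory list had a median of 0.0 over 8 of 23 listed genes (percentile 38.4, S100A9 0.24, NFKB2 −0.18).

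Stress and metabolic lists showed few members apart. In the integrated stress response (median 0.04, 17 genes, percentile 81.5), PHGDH, the first enzyme of serine synthesis, was 1.67-fold higher (173 and 289), while STC2 stood at −0.50 and TRIB3 at 0.28. Endoplasmic reticulum chaperones had a median of 0.05 over 8 of 18 listed genes (percentile 76.6, SDF2L1 0.23, SEL1L −0.11). The heat shock response had −0.02 over 10 of 16 listed genes (percentile 31.0, CHORDC1 −0.52, HSPD1 −0.23). CHORDC1 read 33.6 on the induced array, barely above the floor of 33.5. Cholesterol biosynthesis had a median of 0.04 but a mean of −0.04 over 15 genes (percentile 78.1, FDPS −0.36, IDI1 −0.29). Fatty acid synthesis had a median of 0.02 over 13 genes (percentile 61.7), with the desaturase FADS1 at 0.38 and the elongase ELOVL5 at 0.28. Hypoxia response and glycolysis had −0.05 over 15 genes (percentile 20.7), with PGAM1 at 0.50 and the angiogenic factor VEGFA at −0.34.

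Lists for basic cell functions lay close to 0. The mitochondrial ribosome had a median of 0.06 with 22 of 29 genes above 0 (percentile 95.8, MRPS7 0.51, MRPS28 0.35). The nuclear-encoded respiratory chain had 0.06 over 10 of 38 listed genes (percentile 84.6, CYC1 0.25, UQCRC1 0.24). The cytosolic ribosome had −0.01 over 23 genes (percentile 43.7, RPL32 −0.87, RPL22 −0.35). Apoptosis regulators had 0.06 over 17 genes (percentile 73.6, BBC3 0.28, CFLAR −0.27, BCL2L11 −0.26), and endocytosis and lysosome genes had 0.04 over 13 genes (percentile 77.8, CTSD 0.22, SNX17 0.19). Housekeeping genes had 0.04 over 14 genes (percentile 78.2), with PPIA at −0.61 and CHMP2A at 0.48. PPIA and RPL32 have many processed pseudogenes, so their clusters are uncertain. Few markers of other cell types could be read. Of 14 fibroblast and stromal markers 4 were in the probe table and 2 were measured (TAGLN −0.15, THY1 0.09, median −0.03), and of 16 leukocyte and endothelial markers 9 were in the probe table and 3 were measured (CD68 −0.36, CLDN5 0.18, CD2 0.08, median 0.08).

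**Figure D3:**
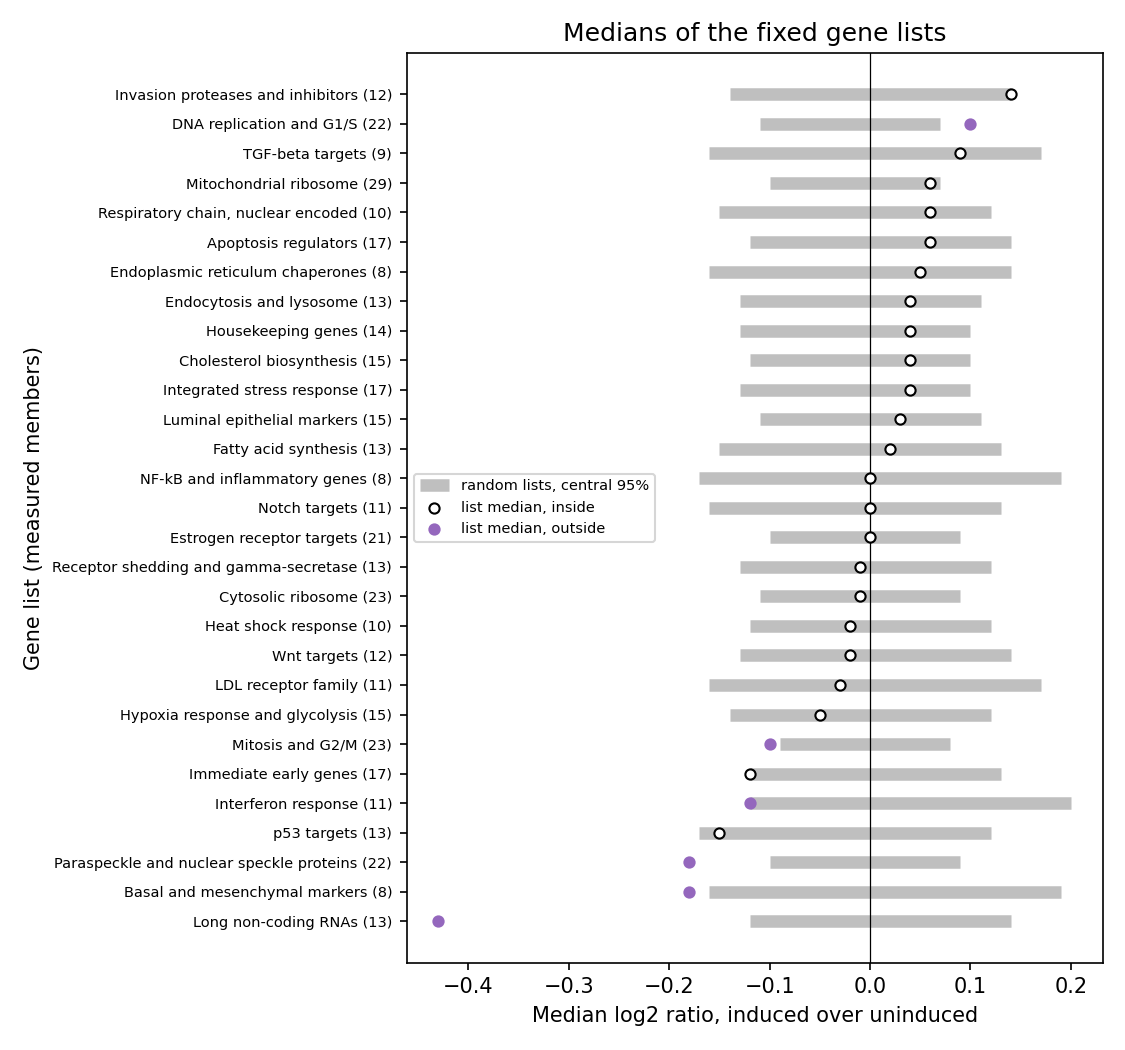
Median log2 ratio of induced over uninduced signal for the 29 gene lists with at least 5 measured members (number in brackets), as points, over grey bars that show the range of the medians of 10000 random lists matched on signal without the outer 2.5% on each side. Filled points lie outside the bar; long non-coding RNAs lie farthest out at −0.43 and DNA replication is the only list above, at 0.10.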

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

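Signals outside the named genes stood out. Of the 37519 clusters without a name here, 14550 were measured on both arrays, and 17 of these were at least 2-fold higher and 471 at least 2-fold lower on the induced array. Among 10993 measured named clusters, 6 were at least 2-fold higher and 23 at least 2-fold lower. The lower readings gathered in clusters whose numbers come before the first named cluster. There 1313 were measured, with a median log2 ratio of −0.42, and 265 (20.2%) were at least 2-fold lower against 2 higher. The other 13237 measured unnamed clusters had a median of 0.03, with 206 at least 2-fold lower and 15 higher. What these clusters read was not given in the sources used here, so neither a technical nor a biological account of them was tested.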

How the results depend on the processing

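Protein-coding genes alone and span centring were chosen after the data were seen. The 2-fold counts of 6 higher and 22 lower became 3 and 13 with the floor at the 75th percentile, 2 and 8 with a pseudocount equal to the floor, 53 and 219 at 1.5-fold, 1 and 3 at 3-fold, and 0 and 0 when every one of 2 or more clusters had to pass, each by construction stricter or looser. Median scaling gave 14 lower and protein-coding genes alone 13 lower. Of 28 genes past 2-fold, 20 remained under median scaling, 21 under quantile normalization, 26 under lowess centring and 10 with the pseudocount. No list that stood apart reversed, and 260 of 287 list values kept their side of the random range. Lists that moved inside it were basal and mesenchymal markers (−0.13 after span centring, −0.14 without the largest member), mitosis (−0.04 quantile, −0.07 lowess, −0.09 span, −0.07 without the largest member), DNA replication (0.10 against unmatched lists) and interferon (−0.05 median scaling, −0.13 lowess, −0.09 floor at the 25th percentile, −0.12 span, −0.12 unmatched, −0.09 without the largest member). Lists that moved outside were p53 targets (−0.15 lowess, −0.16 floor at the 75th percentile, −0.15 unmatched), immediate early genes (−0.09 quantile, −0.15 lowess, −0.21 span, −0.12 unmatched), invasion (0.21 median scaling, 0.14 lowess, 0.11 pseudocount), fatty acid synthesis (0.14) and apoptosis (0.13), both with the floor at the 75th percentile, and the mitochondrial ribosome (0.15 quantile, 0.06 span). The cause was not tested. The long non-coding RNA and speckle lists stood apart in every alternative run. No named gene was marked as reversed in any alternative that gave it a value. All 174 had a value except with the floor at the 75th percentile (115) and under quantile normalization (173). Ratios near 0, such as TFF1 at −0.02, could still change sign, since median scaling raised the median of all genes from 0.016 to 0.084. By more than the spread between clusters, 34 values moved, 33 of them with the pseudocount. Leaving out ambiguous probe sets by ID suffix was not run, since the IDs are numeric. No paired analysis was possible because each group has 1 array.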

Other observations

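The tests of microRNA clusters against host genes, of neighbouring genes after span centring, of shuffled windows and of the steps in the values were chosen after the results they measure were seen, and both lists and the span centring used here were made after the main results. Other genes between 1.5-fold and 2-fold were picked after their values were seen. On the induced array the C-type natriuretic peptide gene NPPC had a log2 ratio of 0.98. Monoamine oxidase B, MAOB, had 0.93, with an uninduced signal of 37.7 close to the floor. The lectin CD22 had 0.90 and the heparin-binding growth factor midkine, MDK, had 0.92 (909 uninduced, 1718 induced). PLAC8 stood at 0.83, the transcription factor CREB3L1 at 0.75, argininosuccinate synthase, ASS1, at 0.73, the neuropeptide receptor NPY1R and the actin-severing protein SCIN each at 0.70, and the retinoic acid-binding protein CRABP2 and the actin-binding TMSB10 each at 0.67. In the other direction, endothelin 1, EDN1, stood at −0.95, the ceramidase ACER2 at −0.93, the epidermal transcription factor GRHL3 at −0.91 and the plakin EPPK1 at −0.90.

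PHGDH prompted a list of 12 serine and one-carbon synthesis genes, of which 9 were measured. PHGDH (0.74), TYMS (0.29), PSAT1 (0.20), SHMT2 (0.16) and PSPH (0.0) belong to lists already read, so the list's place among random lists is no independent evidence and is not given. The other members were GLDC at 0.18, MTHFD2L at 0.13, SHMT1 at 0.04 and MTHFD1L at −0.01.

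The lower speckle protein and long non-coding RNA lists held after lowess centring (−0.18 and −0.40) and after span centring (−0.21 and −0.52), which argues against signal-dependent scaling and gene span as the whole cause. A separate list of 37 transcripts known for detained introns, which shares only CLK4 with the speckle list and whose member DDX5 had been seen before, was lower too, with a median log2 ratio of −0.45 over 26 genes at percentile 0.0 and 25 of 26 below 0. CCNL2 stood at −0.87, PNISR at −0.81, CCNL1 at −0.74 and HNRNPH1 at −0.72, against LUC7L2 at 0.34. That transcripts with detained introns were lower as a class stays a hypothesis. Like the speckle list, this list holds splicing factors and their kinases, such as SRSF4 and CLK2. Its lower median therefore cannot tell detained introns apart from splicing factor transcripts. Retention in the nucleus itself was not tested, and the 565 measured long non-coding RNA genes as a whole had a median of 0.0. A lower share of all unspliced RNA stays open, because microRNA clusters minus host genes gave a median of 0.06 (95% bootstrap interval 0.02 to 0.13, 131 pairs) while following host signal too weakly (Spearman rho 0.23 across pairs) to decide, and neither RNA handling nor doxycycline can be separated from the domain with 1 array each.

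Protein-coding genes of longer genomic span had lower ratios, from a median of 0.11 in the shortest of 10 equal groups (median span 2.6 kb) to −0.06 in the longest (225 kb), with a Spearman rho of −0.24 across genes. The rho was −0.23 after lowess centring, which argues against signal-dependent scaling, and neighbouring genes also had similar ratios, with a rank correlation of 0.18 over 9075 pairs and of 0.16 after span centring, where the highest of 100 shuffles gave 0.02, so span is not the whole account. The most extreme of 7971 windows of 50 genes, from ANKRD36B to TTL, had a median of −0.30. Before rounding, this fell just short of the bound of 0.3 in size set beforehand for a copy number difference between the cultures. The predicted outcome was therefore not met, but so narrowly that such a difference cannot be told apart from regional expression. In 100 shuffles of the genes the most extreme window reached at most 0.19. Shuffling removes any likeness of neighbours, so it cannot separate these accounts. The window from ANKRD36B to TTL holds 6 genes of the RGPD, RANBP2 and ANKRD36 families, which have close copies (median −0.86, the other 44 −0.26). Base composition was not tested, as no genome sequence was used here, and no biological explanation was tested.

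The deposited values carry a trace of their processing. Between 100 and 1000, 5.88% of uninduced and 5.53% of induced values fell in 1 shared bin of remainders after division by 0.5, against 0.2% for an even spread, and the next fullest bin held 47 values against 701 on the uninduced array. A separate scale factor for each array, as MAS5 uses, would not leave the same steps on both. Values averaged over both arrays before summarisation, as quantile normalization of the pair does, are a candidate source of the 5.53%, which was not tested further. Signals on such a common scale cannot show a difference in total RNA between the cultures.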
